A study of Homo sapiens with 24 samples.

How the data were processed

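RNA sequencing was done on 24 libraries of the human lymphoma B cell lines HLY1 and DOHH2, grown in 2D or in alginate spheroids (3D), without stromal cells or with primary tonsil stromal cells (TSC). Per the labels' protocols, the co-cultures ran for 3 days in 2D and for 10 days in 3D, cells stained for CD20 and CD73 were sorted, and each library was made from 10 ng of total RNA. The deposited values were raw counts per gene, 1 table for each library, with 58243 Ensembl gene identifiers. Per the submitters' processing notes, FastQC, STAR, Subread and DESeq2 were used by the authors, with no versions, and the builds hg18 and hg38 were named with no role. The strand setting and the treatment of reads shared between genes are not given in the sources used here. Counts of antisense or overlapping genes, pseudogenes such as ASNSP1, histones, HLA genes and mitochondrial genes with nuclear copies are therefore uncertain where reads could be split. Symbols were matched for 57532 identifiers, 57980 were in GENCODE release 29, whose GRCh38 coordinates are given, and 263 had no name.

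Groups were taken from the labels, which give 7 groups. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No library was a copy of another: the smallest chi-square per degree of freedom was 3.34 between libraries of a group and 8.22 over the 245 pairs between groups, for genes with at least 20 counts. Total counts per library ran from 23907874 to 48586979, and this number of counts limits the precision of low genes.

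Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM scaling, glmQLFit and glmQLFTest). P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Each line was fitted apart with all its groups (12 libraries each), which left 18843 genes and 8 residual degrees of freedom in HLY1 and 16901 genes and 9 in DOHH2. Differences between the lines were fitted on all 24 libraries, with 21010 genes and 17 residual degrees of freedom. The biological coefficient of variation was 0.0835, 0.230 and 0.170 in these fits, and TMM factors ran from 0.943 to 1.10, from 0.959 to 1.05 and from 0.920 to 1.13. Levels are given as CPM (TMM-scaled) with the SD over libraries. The 8 comparisons of 2 groups and the 3 interactions were fixed before the data were examined, as were the alternatives except 4 that were added later.

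For 23 gene lists fixed at the same time (435 genes, 1 of them not matched), camera of limma 3.58.1 was run with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The lists were stromal cell markers, markers of T, myeloid, epithelial and endothelial cells, B cell identity, germinal centre programme, plasma cell differentiation, and hypoxia and glycolysis. Metabolic and growth lists were cell cycle, MYC and ribosome biogenesis, cholesterol biosynthesis, amino acid stress response (ATF4 targets), endoplasmic reticulum chaperones, oxidative phosphorylation, mitochondrially encoded genes and replication-dependent histones. Signalling and immune lists were interferon response, NF-kB targets, B cell receptor and immediate early genes, MHC class II, MHC class I presentation, apoptosis regulators, p53 targets, adhesion and migration receptors, and immune checkpoint and costimulatory molecules. Counts of list members are given over all genes tested, and the count adjusted over the list alone is given where it differs.

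Genes were named by a rule fixed before the data were examined. For comparisons of 2 groups, the 8 higher and the 8 lower genes with the largest change were taken among those past the threshold. They needed a mean of at least 5 CPM in the higher group, no overlap between the groups' libraries and a gene symbol, and lay outside the stromal list and the Y chromosome. For interactions, 5 each way were taken without the overlap condition. Up to 2 called members each way of every list were added, and MS4A1, NT5E and the stromal list were always included. Some genes of this selection were left out for length, and some are not reported. Where every library of a group was at 0, a fold is a lower bound set at 3 counts over the group, and with 1 to 3 counts the ratio is given with its counting interval, which covers counting error only.

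Alternatives were DESeq2 1.42.0, DESeq2 size factors, no filter on low counts, a mean of at least 5 CPM, the replicate number as a block, and only the 2 groups compared. Each library was also left out in turn, as were 241 genes that stromal RNA could raise. These were the stromal list and genes over 5 times higher with TSC in HLY1 2D, HLY1 3D and DOHH2 2D alike, picked from these same data. The p-values of the other genes were only adjusted again. Added after the data were seen were scaling by library size only, leaving out the 2 libraries richest in stromal transcripts, a stromal score as a covariate, and counting only genes of at least 5 CPM in DOHH2 2D alone. The test was checked on simulated data with 200 changed genes: 74.2% of 2-fold and 94.9% of 4-fold changes were recovered for the stroma comparison of HLY1 in 2D (18116 genes). Of the calls, 6.74% were false. The same shares were 56.7%, 79.0% and 1.47% for stroma in DOHH2 in 2D (16579 genes) and 58.6%, 76.3% and 5.71% for 3D against 2D in DOHH2 with stroma (16577 genes). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.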

Results

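The study's title names 3D co-cultures of B lymphoma cells, and its groups ask how culture in spheroids and the presence of stromal cells change expression in such cells. Gene counts were measured in 24 libraries from 7 groups. HLY1, an established B cell lymphoma line, was grown in 2D alone, in 2D with primary tonsil stromal cells (TSC), in alginate spheroids (3D) alone and in 3D with TSC, with 3 libraries in each group. DOHH2, another such line, was grown in 2D alone (4 libraries), in 2D with TSC (3 libraries) and in 3D with TSC (5 libraries), and DOHH2 in 3D alone was not analysed here. Total counts per library ran from 34663335 to 48586979 in HLY1 and from 23907874 to 38691605 in DOHH2. Co-cultures lasted 3 days in 2D and 10 days in 3D, so dimension and culture time changed together, and the length of the monocultures is not given in the sources used here.

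**Figure D1:**
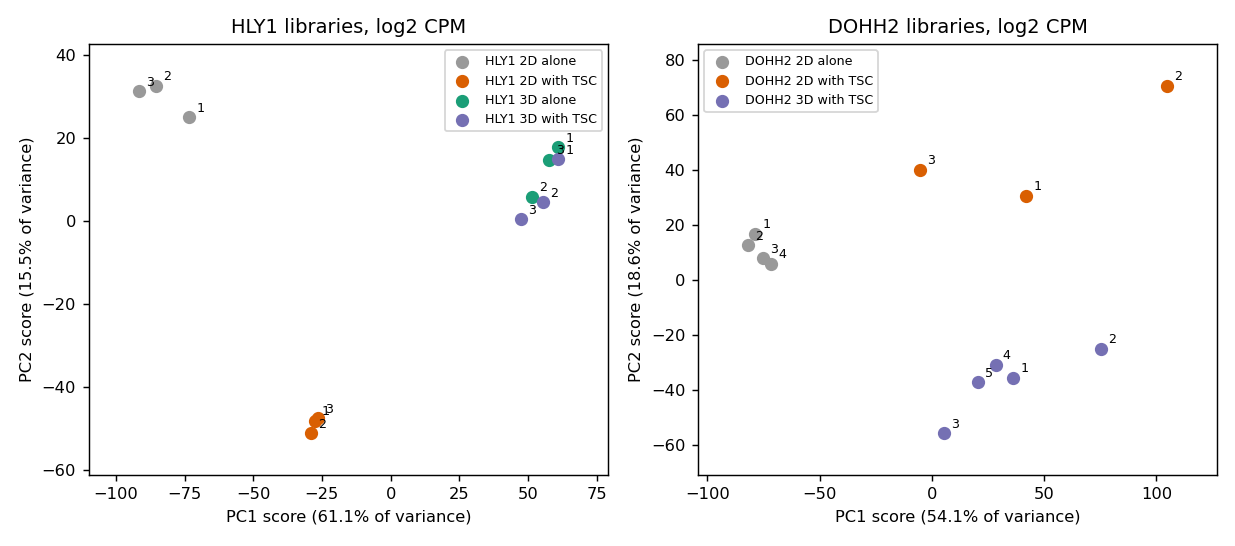
Principal components of log2 CPM for the 12 libraries of each line, with PC1 and PC2 on the axes as percent of variance, colours for groups and numbers for replicates. PC1 held 61.1% of the variance in HLY1 and 54.1% in DOHH2, and HLY1 libraries of 3D alone and 3D with TSC lay side by side.

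CD20, encoded by MS4A1, and CD73, encoded by NT5E, were the proteins stained for the sort. In DOHH2, MS4A1 stood at 856 ± 135 CPM (mean ± SD, n = 4) in 2D alone, 1088 ± 99.9 CPM (n = 3) in 2D with TSC and 862 ± 117 CPM (n = 5) in 3D with TSC. In HLY1 it was below 1 CPM in every group, at 0.293 ± 0.114 CPM in 2D alone and 0.0807 ± 0.115 CPM in 3D with TSC (n = 3 each), although the labels describe sorted CD20-positive cells. SDC1, the plasma cell surface protein syndecan-1, stood at 87.8 ± 14.8 CPM in HLY1 2D alone and 211 ± 7.68 CPM in 2D with TSC (n = 3 each). NT5E was at 0 in all 4 DOHH2 monocultures. It was at 7.13 ± 10.7 CPM (n = 3) with TSC in 2D, at least 328-fold higher, and at 1.29 ± 1.41 CPM (n = 5) in 3D, at least 50.9-fold higher. Without replicate 2 of each co-culture, the library richest in stromal transcripts, these bounds for NT5E were 37.2-fold and 28.2-fold.

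The 27 genes of the stromal list, such as collagens and fibronectin, summed to 7.42 to 9.69 CPM of total counts, with no TMM scaling, in DOHH2 2D alone, 222 to 2934.5 in 2D with TSC and 76.9 to 1495 in 3D with TSC. In HLY1 the same sum was 461 to 672 in 2D alone, 852 to 888 in 2D with TSC, 420.1 to 449.8 in 3D alone and 512 to 542 in 3D with TSC. FBN1 alone stood at 453 CPM in HLY1 2D alone. In 2D alone, 8 of the 22 list genes tested in HLY1 stood at 1 CPM or more, and 2 of 26 in DOHH2. Mitochondrially encoded genes took 2.74% ± 1.08 (SD, n = 4) of DOHH2 counts in 2D alone, 6.69% ± 0.750 (n = 3) in 2D with TSC and 6.74% ± 0.968 (n = 5) in 3D with TSC. In DOHH2 2D alone the share was 1.86% and 1.77% in replicates 1 and 2, and 3.45% and 3.87% in replicates 3 and 4. In HLY1 mitochondrially encoded genes took 6.01% ± 0.806 in 2D alone, 6.04% ± 0.550 in 2D with TSC, 4.70% ± 0.197 in 3D alone and 4.44% ± 0.207 in 3D with TSC (n = 3 each).

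**Figure D2:**
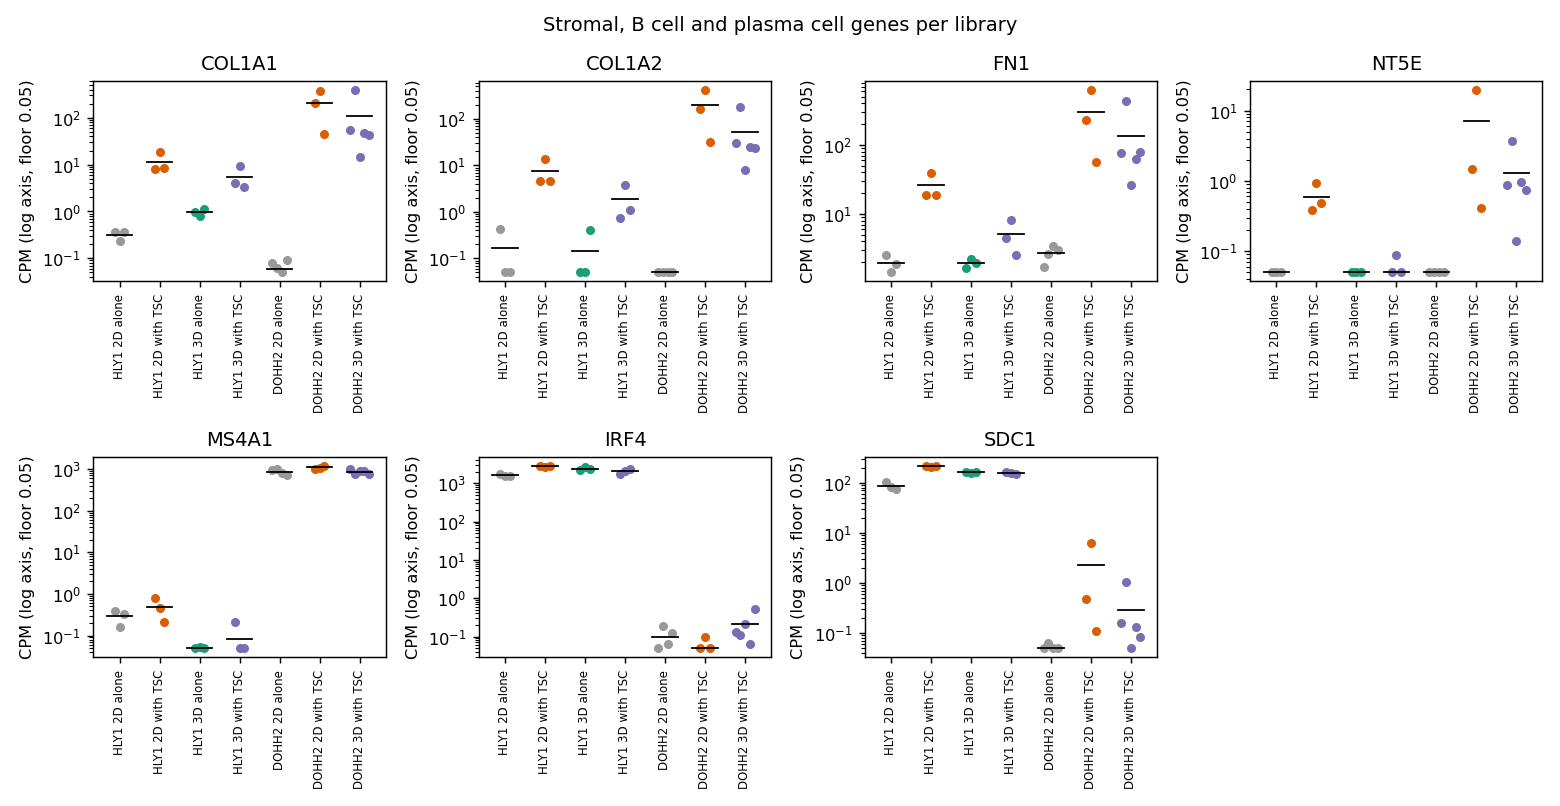
CPM per library (points, log axis, values under 0.05 drawn at 0.05) with the group mean (bar) for stromal genes, NT5E, MS4A1 and plasma cell genes in the 7 groups. MS4A1 lies at 856 ± 135 CPM (mean ± SD, n = 4) in DOHH2 2D alone and below 1 CPM in every HLY1 library.

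With TSC in 2D, HLY1 libraries held more RNA of plasma cell, cholesterol synthesis, chaperone and interferon genes and less of amino acid stress genes than HLY1 alone. Stromal transcripts rose as well, in 16 of 22 members of the stromal list, with COL1A1 (5.17) and FN1 (3.72) by log2 fold change, and so did markers of other cells in 4 of 7, and which cells held the RNA was not tested in HLY1. The list calls of cholesterol and chaperone genes did not hold with an estimated correlation (0.0663 and 0.0541). JCHAIN, the joining chain of secreted antibodies, rose from 182 ± 29.2 to 837 ± 43.0 CPM (mean ± SD, n = 3 in each group; log2 fold change 2.20, SE 0.12, edgeR adjusted p = 1.32e-09). ASNS, asparagine synthetase (ENSG00000070669, chromosome 7, 97852118 to 97872542), fell from 37.8 ± 3.75 to 5.63 ± 0.285 CPM (log2 fold change -2.75, SE 0.10, edgeR adjusted p = 2.95e-11). Of 18843 genes tested, 9286 changed, 4424 higher and 4862 lower, and 2244 changed by at least 2-fold. By the naming rule, which leaves out the stromal list, the largest changes upward, as log2 fold changes in brackets, included IGFBP5 (5.92), CCL3 (4.80), DUSP5 (4.37), ST3GAL6 (3.85), GPRC5D (3.78) and FOSB (3.68). The largest downward were in MOV10L1 (-5.01), BEST1 (-4.26), ESRP1 (-4.15), ASNSP1 (-4.02), PLOD2 (-3.81) and TBC1D8 (-3.61). IGFBP5 was at 0 in DOHH2 monocultures and at least 8692-fold higher there with TSC in 2D, or 3046.7-fold without replicate 2 of that co-culture. Without HLY1 2D alone replicate 1 its value was 7.65, and without replicate 3 that of ESRP1 was -3.44. With library size as the only scaling, the median of all genes moved by -0.11 and 34.6% of changed genes were higher, against 47.6%.

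By camera, 13 of 23 gene lists were called in HLY1 with TSC in 2D, and each adjusted p is given with the preset and then with the estimated correlation. Among plasma cell genes, 12 of 16 tested members rose and 0 fell (camera adjusted p = 3.79e-10, then 0.0334), among them PRDM1, a transcription factor of plasma cell differentiation (log2 fold change 1.07). Targets of ATF4 in the amino acid stress response fell in 16 of 17 cases with a median of -1.91 (3.82e-40, then 0.0139), among them PSAT1 of serine synthesis (-2.25). Cholesterol genes rose in 16 of 17 (2.31e-22, then 0.0663), with LSS (1.53). Endoplasmic reticulum chaperones rose in 12 of 15 and EDEM1 fell (1.98e-16, then 0.0541), with CALR (1.28) and PDIA4 (1.36). Interferon genes rose in 11 of 16 (0.00117, then 0.0334), with ISG15 (0.99) and OAS2 (0.61). Adhesion and migration receptors rose in 10 of 15, 11 when adjusted over the list alone (1.71e-08, then 0.00788), with PECAM1 (2.70) and SELPLG (1.05).

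Several more lists were called in HLY1 with TSC in 2D by the preset correlation only. Immediate early genes rose in 12 of 14, 14 over the list alone (camera adjusted p = 2.05e-06, estimated 0.191), with JUNB (1.22) and DUSP5 (4.37) by log2 fold change. In CPM, EGR1, FOS and FOSB together rose by 0.0915 of the rise of the stromal list, 80.3% of which came from genes of at least 10 CPM in HLY1 alone. MHC class I genes rose in 10 of 14 and 1 fell (0.00117, estimated 0.122), with TAPBP (0.73) and TAP1 (0.60). NF-kB targets rose in 9 of 14, with 1 lower over the list alone (0.0248, estimated 0.453). Histones rose in 9 of 15 (5.38e-05, estimated 0.0571), with H1-2 (1.69). Checkpoint molecules rose in 9 and fell in 1 of 14, 10 higher over the list alone (0.00718, estimated 0.175), with TNFSF9 (1.27) and CD70 (0.78). T, myeloid, epithelial and endothelial markers rose in 4 of 7 (0.0356, estimated 0.122). The stromal list rose in 16 of 22 and fell in 2 (1.38e-06, estimated 0.175), with COL1A1 (5.17), FN1 (3.72), TAGLN (-0.59) and ACTA2 (-0.71). The MHC class II list was not called (0.111), although 8 of 12 members fell, among them HLA-DRA (-0.97) and CD74 (-0.54), and 2 rose.

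**Figure D3:**
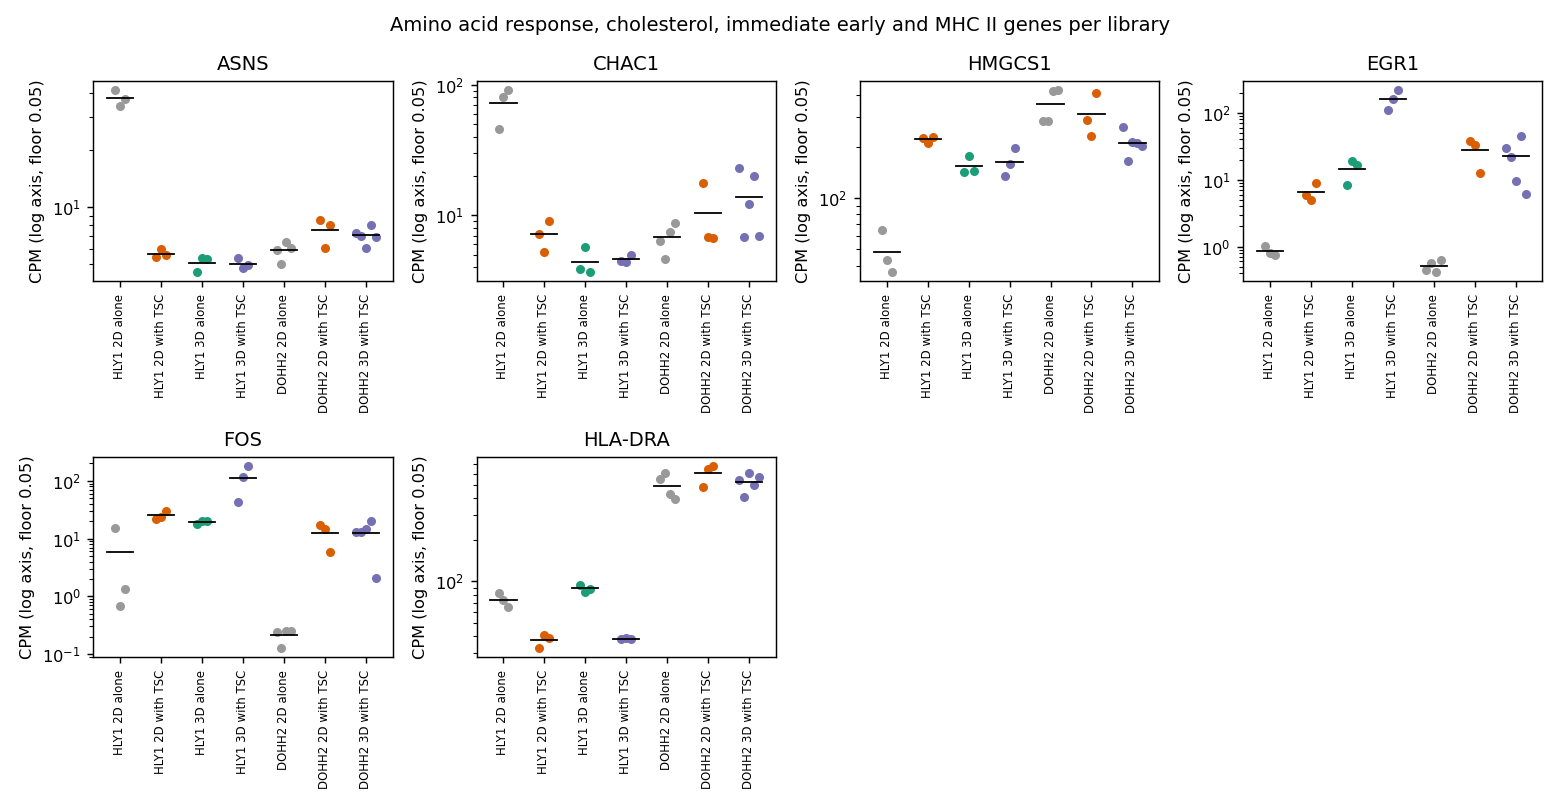
CPM per library (points) with the group mean (bar) for ASNS, CHAC1, HMGCS1, EGR1, FOS and HLA-DRA in the 7 groups. ASNS fell from 37.8 ± 3.75 to 5.63 ± 0.285 CPM (mean ± SD, n = 3 each) with TSC in HLY1 2D.

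In 3D, TSC changed far fewer HLY1 genes, with immediate early genes higher and MHC class II genes lower. The list call of immediate early genes did not hold with an estimated correlation (0.165). EGR1, an immediate early transcription factor (ENSG00000120738, chromosome 5, 138465490 to 138469315), rose from 14.6 ± 5.64 to 163 ± 53.6 CPM (mean ± SD, n = 3 each; log2 fold change 3.48, SE 0.27, edgeR adjusted p = 5.34e-06). HLA-DRA, the alpha chain of an MHC class II molecule (ENSG00000204287, chromosome 6, 32439842 to 32445046), fell from 88.6 ± 5.14 to 38.4 ± 0.381 CPM (log2 fold change -1.21, SE 0.09, edgeR adjusted p = 2.63e-06). CD74, the invariant chain of that molecule, fell from 98.5 ± 7.18 to 47.3 ± 0.752 CPM (log2 fold change -1.06, SE 0.08, edgeR adjusted p = 2.63e-06). Of 18843 genes tested, 306 changed, 139 higher and 167 lower, 70 of them by at least 2-fold, and 2542 had an unadjusted p under 0.05. Without 3D alone replicates 1, 2 and 3 in turn the count was 134, 169 and 121, and without 3D with TSC replicates 2 and 3 it was 109 and 149. Other genes higher with TSC, as log2 fold changes, were RGS1 (2.16), TSC22D3 (1.93), SOCS3 (1.76), RGS2 (1.55), H2BC21 (1.60) and BACH2 (0.64). Lower were NUAK1 (-1.20), NFKBIZ (-1.13), S1PR1 (-0.61), NDRG1 (-0.46), NFKBIA (-0.75) and TNFAIP3 (-0.79).

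FOS rose with TSC in HLY1 3D from 19.5 ± 1.29 to 114 ± 69.5 CPM (mean ± SD, n = 3 each; log2 fold change 2.54, SE 0.61, edgeR adjusted p = 0.0475), but its adjusted p was 0.169, 0.127 and 0.158 without 3D alone replicates 1, 2 and 3, 0.138 and 0.199 without 3D with TSC replicates 2 and 3 and 0.152 with DESeq2. It also missed the threshold with the replicate block and with the 5 CPM filter. By list, MHC class II fell in 7 of 12, 8 over the list alone (camera adjusted p = 6.77e-30, 0.000124 with an estimated correlation). Immediate early genes rose in 5 of 14, with 8 higher and 2 lower over the list alone (6.02e-09, estimated 0.165). NF-kB targets fell in 4 of 14, 5 over the list alone (3.14e-06, estimated 0.165). Interferon genes fell in 2 of 16 (0.00163, estimated 0.0331), and adhesion receptors fell in 3 and rose in 1 of 15, with 5 lower over the list alone (8.39e-05, estimated 0.0331). Histones rose in 3 of 15, with 8 higher and 1 lower over the list alone (7.50e-07, estimated 0.0331). The stromal list rose in 4 of 22, 10 over the list alone (1.31e-14, estimated 0.0528). With 0 members called, cholesterol genes were called higher (0.00894, estimated 0.811) and chaperones (0.0412, estimated 0.811) and mitochondrially encoded genes (0.0126, estimated 0.811) lower.

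The effect of TSC in HLY1 differed between dimensions for 6558 genes, 3246 higher and 3312 lower in 3D. The differences of log2 fold change were 2.73 for ASNS, 2.13 for PSAT1, -1.32 for CALR, -2.17 for JCHAIN and -2.79 for PECAM1. The median log2 fold change of ATF4 targets with TSC was -0.01 in 3D and -1.91 in 2D, so their difference reflects the fall in 2D and no rise in 3D. Without TSC these targets were already lower in 3D than in 2D, at a median of -1.75, and 3D with TSC stood at -1.73 against 2D alone. The 2D alone group was thus higher than every other HLY1 group. Whether TSC would lower these targets in 3D from a higher level was not tested. As differences, ATF4 targets were higher in 16 of 17 (camera adjusted p = 1.13e-37, estimated 0.0138) and cholesterol genes lower in 16 of 17 (2.38e-17, estimated 0.121). Lower too were 12 of 16 plasma cell genes (1.24e-09, estimated 0.0364), 10 of 16 interferon genes (7.41e-05, estimated 0.0138) and 12 of 15 chaperones, 13 over the list alone, with 1 higher (8.38e-18, estimated 0.0449). Adhesion receptors were lower in 11 of 15, 13 over the list alone, with 1 higher (2.48e-11, estimated 0.00276). With library size as the only scaling, 65.2% of these genes were higher, against 49.5%, with a median shift of 0.12. Of the genes called in both dimensions, 113 changed in the same direction (75.7 for independent lists) and 87 in opposite directions (75.1). Pearson r of the fold changes was 0.09 and Spearman rho -0.02 across 18843 genes, which are not independent replicates.

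In HLY1 alone, 3D culture raised replication, ribosome biogenesis, cholesterol and oxidative phosphorylation genes and lowered ATF4 and p53 targets. None of these list calls held with an estimated correlation. MCM7, part of the replicative helicase (ENSG00000166508, chromosome 7, 100092728 to 100101940), rose from 746 ± 59.8 to 2119 ± 82.1 CPM (mean ± SD, n = 3 each; log2 fold change 1.51, SE 0.07, edgeR adjusted p = 7.99e-11). CDKN1A, the p53 target p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339), fell from 358 ± 24.4 to 112 ± 11.9 CPM (log2 fold change -1.67, SE 0.09, edgeR adjusted p = 4.25e-10). Of 18843 genes, 12662 changed, 5933 higher and 6729 lower, and 5010 by at least 2-fold. The largest increases, as log2 fold changes, included CCR7 (4.06), FUT7 (5.23), CCL3 (6.13), DUSP5 (5.20), SFN (4.63) and EGR1 (4.09). The largest decreases included BEST1 (-7.05), LINC02475 (-6.45), ESRP1 (-6.41), SPOCK3 (-6.14) and PLOD2 (-5.77). Without single libraries these became 4.75 for CCR7 (2D alone replicate 1), -5.70 for ESRP1 (2D alone replicate 3), -6.76 for SPOCK3 (3D alone replicate 1) and 5.17 for CCL3 (3D alone replicate 2). MOV10L1 was at 0 in 3D alone, at least 313-fold lower. With library size as the only scaling, the median moved by -0.20 and 33.8% of changed genes were higher, against 46.9%.

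For 3D in HLY1 alone, cell cycle genes rose in 22 of 25 (camera adjusted p = 3.02e-13, estimated 0.390) and MYC and ribosome genes in 19 of 20 (3.83e-12, estimated 0.170). So did cholesterol genes in 16 of 17 (6.16e-07, estimated 0.439) and oxidative phosphorylation genes in 15 of 22 (0.000399, estimated 0.509). ATF4 targets fell in 17 of 17 with a median log2 fold change of -1.75 (1.81e-18, estimated 0.131). P53 targets fell in 12 of 16 and rose in 1, with 13 lower over the list alone (1.24e-05, estimated 0.148). Chaperones rose in 11 of 15 and fell in 2 (0.00577, estimated 0.509), NF-kB targets rose in 11 of 14 and fell in 3 (0.00115, estimated 0.439), and immediate early genes rose in 12 of 14 (0.000190, estimated 0.439). Adhesion receptors rose in 9 of 15 and fell in 5 (0.000505, estimated 0.123), and histones rose in 11 of 15 and fell in 1 (0.00500, estimated 0.273). Log2 fold changes were 1.27 for NCL, -2.90 for ASNS, 0.98 for CYC1 and -1.47 for FAS. The stromal list, with 3 members higher and 9 lower of 22, was not called (0.164), at a median of -0.79, or -0.46 with the genes at the floor set to their bound.

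With TSC present, 3D against 2D raised cell cycle, ribosome and oxidative phosphorylation genes in HLY1 and lowered plasma cell, chaperone, MHC and p53 genes. Of these list calls, 0 held with an estimated correlation. ABCA1, a cholesterol exporter (ENSG00000165029, chromosome 9, 104781002 to 104928237), rose from 14.6 ± 1.62 to 94.1 ± 12.3 CPM (mean ± SD, n = 3 each; log2 fold change 2.69, SE 0.12, edgeR adjusted p = 1.50e-09). TRIM22, an interferon-induced protein (ENSG00000132274, chromosome 11, 5689689 to 5737089), fell from 11.6 ± 1.12 to 1.12 ± 0.270 CPM (log2 fold change -3.40, SE 0.19, edgeR adjusted p = 5.71e-09). Of 18843 genes, 9979 changed, 4876 higher and 5103 lower, and 2626 by at least 2-fold. With library size as the only scaling, the median moved by -0.08 and 39.9% of changed genes were higher, against 48.9%. Other increases, as log2 fold changes, were in EGR1 (4.64), CCR7 (2.34), MT1E (1.98) and CDCA7 (1.95), and decreases in SPOCK3 (-5.81), CAMK1D (-5.02), NLRP7 (-4.97), MYO10 (-4.10), CSF2RB (-3.72) and NFATC2 (-3.50). Of genes called both here and in 3D against 2D alone, 7208 had the same direction (3357.6 for independent lists) and 676 the opposite (3348.0), with Pearson r 0.68 and Spearman rho 0.66.

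In the lists for 3D against 2D with TSC in HLY1, higher were cell cycle genes in 25 of 25 (camera adjusted p = 1.70e-19, estimated 0.162) and MYC and ribosome genes in 19 of 20 (1.54e-15, estimated 0.0825). Oxidative phosphorylation genes rose in 16 of 22 (0.000114, estimated 0.329) and immediate early genes in 9 of 14 (0.00411, estimated 0.411). Lower were plasma cell genes in 11 of 16, with 1 higher (0.000374, estimated 0.162), and chaperones in 11 of 15 (4.16e-06, estimated 0.233). MHC class I genes fell in 9 of 14, with 1 higher (2.05e-05, estimated 0.0825). Interferon genes fell in 11 of 16 and 1 rose, 2 over the list alone (0.000215, estimated 0.0595), and MHC class II genes fell in 7 of 12 and 2 rose (0.000153, estimated 0.0595). P53 targets fell in 12 of 16, 13 over the list alone (3.99e-07, estimated 0.0652). Checkpoint molecules fell in 9 of 14, with 1 higher (0.0200, estimated 0.256), and mitochondrially encoded genes in 8 of 13, 9 over the list alone (0.00916, estimated 0.513). The stromal list fell in 22 of 22 (1.19e-06, estimated 0.162), and T and other cell markers in 5 of 7 (0.0262, estimated 0.146). Log2 fold changes were 1.16 for MCM6, 0.91 for NOLC1, -1.24 for JCHAIN, -0.96 for HSP90B1, -1.09 for CD74, -1.62 for CDKN1A and -3.09 for COL6A3.

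HLY1 in 3D with TSC against 2D alone, where dimension and stroma changed together, differed in 12609 of 18843 genes, 5972 higher and 6637 lower, and 4959 by at least 2-fold. EGR1 rose from 0.853 ± 0.149 to 163 ± 53.6 CPM (mean ± SD, n = 3 each; log2 fold change 7.58, SE 0.37, edgeR adjusted p = 1.63e-10), and CD74 fell from 146 ± 14.7 to 47.3 ± 0.752 CPM (log2 fold change -1.63, SE 0.08, edgeR adjusted p = 1.14e-10). Further log2 fold changes were 4.67 for FUT7, 4.51 for SFN, 5.74 for CCL3, 1.42 for LDHA, -6.97 for SPOCK3 and -5.52 for RUNX1T1. By list, 12 were called and 0 with an estimated correlation. ATF4 targets fell in 17 of 17 (camera adjusted p = 2.93e-20, estimated 0.0986), MHC class II genes in 10 of 12 (9.81e-05, estimated 0.0986) and p53 targets in 13 of 16, with 1 higher (1.01e-05, estimated 0.0986). Immediate early genes rose in 13 of 14 (4.86e-07, estimated 0.295) and cell cycle genes in 22 of 25 (1.16e-12, estimated 0.295). MYC and ribosome genes rose in 19 of 20, with 1 lower (7.14e-12, estimated 0.117), and cholesterol genes in 16 of 17 (4.90e-09, estimated 0.295). Histones rose in 13 of 15 (5.05e-05, estimated 0.0986) and oxidative phosphorylation genes in 16 of 22 (0.000967, estimated 0.572). Chaperones rose in 11 with 3 lower of 15 (0.0247, estimated 0.647), NF-kB targets in 9 with 3 lower of 14 (0.0250, estimated 0.572) and adhesion receptors in 9 with 3 lower of 15 (0.00786, estimated 0.0986). The stromal list, 10 higher and 6 lower of 22, was not called (0.914), at a median of 1.25, or 1.06 with the genes at the floor set to their bound. With library size as the only scaling, the median moved by -0.19 and 34.1% of changed genes were higher, against 47.4%.

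**Figure D4:**
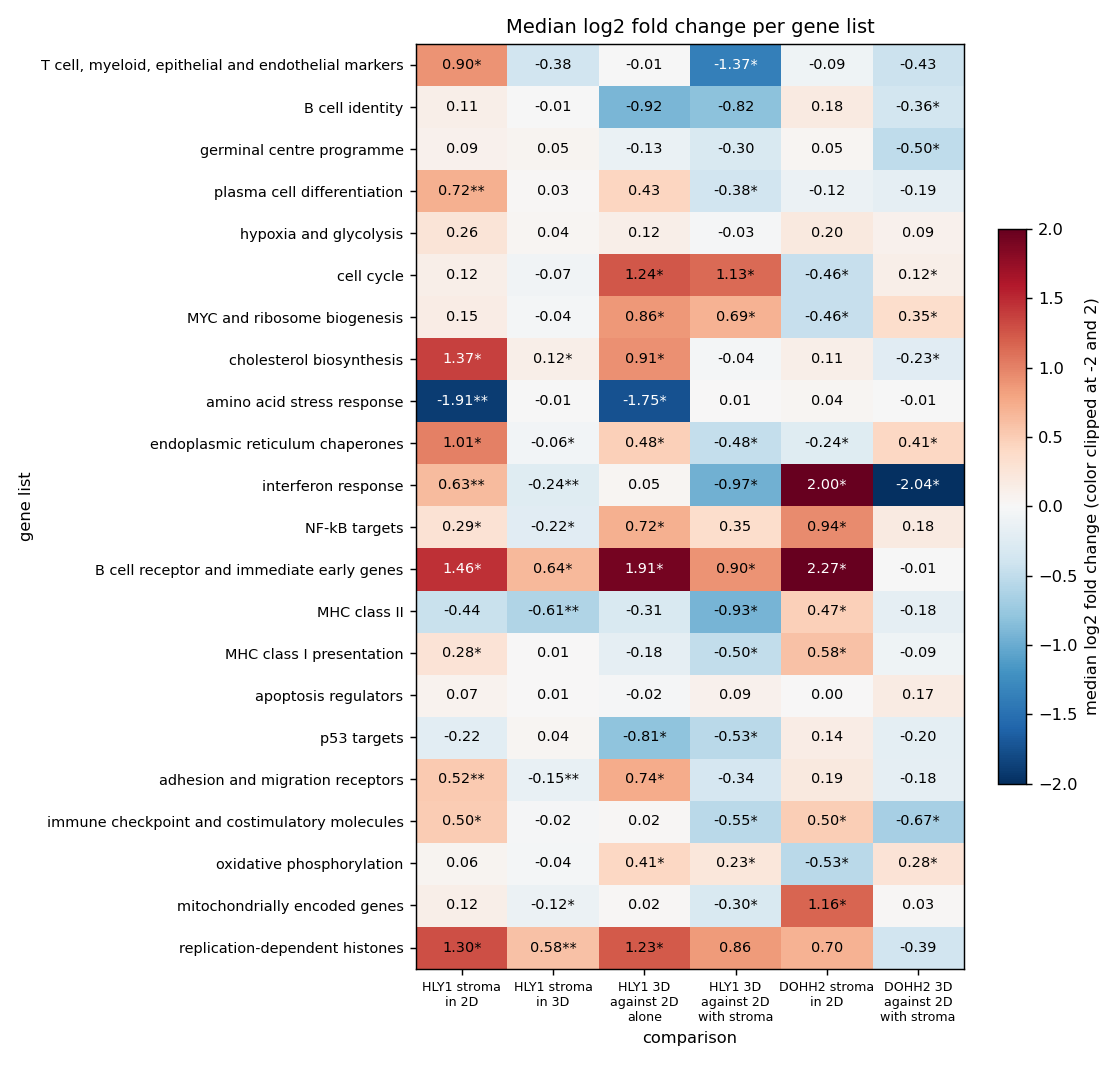
Heat map of the median log2 fold change of 22 gene lists, the stromal list left out, in 6 comparisons of 2 groups, with genes at the floor set to their bound and colours that stop at -2 and 2. A star marks camera adjusted p under 0.05 with the preset correlation and 2 stars also with an estimated correlation, such as ATF4 targets at -1.91 for TSC in HLY1 2D (3.82e-40, estimated 0.0139).

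With TSC in 2D, DOHH2 libraries held stromal transcripts, more RNA of interferon, NF-kB, immediate early and MHC class I genes and less of cell cycle, ribosome and oxidative phosphorylation genes. With an estimated correlation 0 of these list calls held. IRF7, an interferon regulatory factor (ENSG00000185507, chromosome 11, 612553 to 615999), rose from 12.9 ± 2.24 (mean ± SD, n = 4) to 62.9 ± 21.3 CPM (n = 3; log2 fold change 2.28, SE 0.26, edgeR adjusted p = 2.57e-04). NFKB2, an NF-kB subunit (ENSG00000077150, chromosome 10, 102394110 to 102402529), rose from 29.2 ± 4.25 to 80.9 ± 19.5 CPM (log2 fold change 1.47, SE 0.22, edgeR adjusted p = 7.12e-04), and IL7R, the interleukin 7 receptor, fell from 49.4 ± 6.84 to 15.4 ± 0.284 CPM (log2 fold change -1.68, SE 0.33, edgeR adjusted p = 0.00292). Of 16901 genes, 5490 changed, 2937 higher and 2553 lower, and by at least 2-fold 1811 were higher and 93 lower. Among genes of at least 5 CPM in DOHH2 2D alone, 3603 changed and 29.9% of them were higher, against 53.5%. Genes at 0 in all monocultures were higher by at least 8692-fold for IGFBP5, 2974-fold for IGFBP4, 2512-fold for GREM1, 2425-fold for FBN2, 1752-fold for MMP1, 1708-fold for COL12A1, 1568-fold for S100A6, 1442-fold for TIMP2, 1122-fold for CD44 and 105-fold for VSIR. Most of this came from 1 library: without 2D with TSC replicate 2 the bounds were 3046.7, 425, 177, 652, 115, 536, 146, 308, 213 and 48.0-fold for IGFBP5, IGFBP4, GREM1, FBN2, MMP1, COL12A1, S100A6, TIMP2, CD44 and VSIR. COL1A1 stood at 0.0593 ± 0.0414 CPM (n = 4) alone and 209 ± 162 CPM (n = 3) with TSC. Stromal sums and the mitochondrial share differed along with the groups. Without the 2 libraries richest in stromal transcripts, an alternative chosen after the data were seen, 4213 genes changed, 3772 of them shared, and without 2D with TSC replicate 2 the count was 3500.

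With TSC in DOHH2 2D, interferon genes rose in 17 of 21, 21 over the list alone (camera adjusted p = 6.32e-13, estimated 0.152), and 17 of 21 without the 2 libraries richest in stromal transcripts (8.82e-12). NF-kB targets rose in 11 of 17, 13 over the list alone (8.67e-07, estimated 0.152). Immediate early genes rose in 11 of 17, 14 over the list alone (3.17e-07, estimated 0.152), and MHC class I genes in 11 of 14 (1.41e-07, estimated 0.152). In CPM, EGR1, FOS and FOSB together rose by 0.0318 of the rise of the stromal list. Mitochondrially encoded genes rose in 12 of 13, 13 over the list alone (1.14e-10, estimated 0.153). Checkpoint molecules rose in 9 of 19, with 1 lower over the list alone (0.00504, estimated 0.153), and the stromal list in 25 of 26 at a median of 8.82, or 7.94 with the genes at the floor set to their bound (6.90e-19, estimated 0.153). Oxidative phosphorylation genes fell in 21 of 22, with 1 higher over the list alone (1.93e-14, estimated 0.152), and cell cycle genes in 15 of 25, 21 over the list alone (6.97e-10, estimated 0.233). MYC and ribosome genes fell in 16 of 20 (2.85e-09, estimated 0.152) and chaperones in 5 of 15 (0.0357, estimated 0.654). MHC class II genes rose in 5 of 12, 6 over the list alone (0.00405, estimated 0.468), but not with the replicate number as a block (0.0609). Without the 2 libraries richest in stromal transcripts, 11 of 25 cell cycle genes, 15 of 20 ribosome genes and 19 of 22 oxidative phosphorylation genes were lower and 12 of 13 mitochondrially encoded genes higher. Without them chaperones, 1 higher and 2 lower of 15, were no longer called (0.279), while B cell identity genes (4 of 19 higher, 0.0152) and adhesion receptors (5 of 17 higher, 0.0197) were. Log2 fold changes were 2.56 for IFI6, 1.16 for RELB, 5.83 for FOS, 1.47 for MT-ND1, -0.67 for SDHB, -0.92 for CCNB1, -0.66 for POLR1B and 0.66 for CIITA.

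With TSC present, DOHH2 in 3D held less RNA of interferon, B cell and germinal centre genes than in 2D and more of ribosome, oxidative phosphorylation and chaperone genes. Stromal transcripts were lower in 3D too, at a median log2 fold change of -2.03 for the stromal list. By an estimated correlation 0 of the list calls held. RSAD2, an interferon-induced protein (ENSG00000134321, chromosome 2, 6865806 to 6898239), fell from 2.31 ± 1.45 (mean ± SD, n = 3) to 0.0969 ± 0.0504 CPM (n = 5; log2 fold change -4.48, SE 0.53, edgeR adjusted p = 3.69e-04), and ISG15 from 9.31 ± 4.13 to 1.01 ± 0.581 CPM (log2 fold change -3.19, SE 0.40, edgeR adjusted p = 4.13e-04). CBFA2T3, a transcriptional corepressor (ENSG00000129993, chromosome 16, 88874858 to 88977204), fell from 55.0 ± 50.9 to 1.84 ± 0.419 CPM (log2 fold change -4.91, SE 0.45, edgeR adjusted p = 1.81e-04). Of its 3 libraries in 2D with TSC, replicate 3 held 113 CPM of CBFA2T3 and the others 20.2 and 31.4, and without replicate 3 the log2 fold change was -3.82. Of 16901 genes, 3735 changed, 1682 higher and 2053 lower, and by at least 2-fold 205 were higher and 835 lower. The balance depended on the genes counted: 45.0% of the changed genes were higher, against 33.3% with no filter, 51.6% with the 5 CPM filter and 52.2% among genes of at least 5 CPM in 2D alone. Other log2 fold changes were 4.76 for KLRC1, 4.10 for SHROOM2, 2.47 for WNT10A, 2.08 for NELL2, -6.21 for SVEP1, -5.60 for VGLL3, -5.24 for THBS2, -5.19 for ZNF777 and -5.13 for TCL1A. Single libraries moved these values: without 2D with TSC replicate 2 they were 6.45 for KLRC1, 5.42 for SHROOM2, -4.66 for SVEP1, -3.10 for VGLL3 and -4.11 for THBS2. Without replicate 3 they were -3.96 for ZNF777 and -4.46 for TCL1A, and without replicate 1 NELL2 was at 2.75. Without 3D with TSC replicate 2 they were -7.93 for SVEP1, -6.25 for VGLL3 and -6.39 for THBS2, and without its replicate 4 TCL1A was at -6.73. The count was 2340 with only the 2 groups fitted, 2404 with a stromal score as covariate and 3209, with 2558 shared, without the 2 libraries richest in stromal transcripts.

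In 3D against 2D with TSC in DOHH2, interferon genes fell in 17 of 21, 19 over the list alone (camera adjusted p = 7.45e-15, estimated 0.195), and in 14 of 21 without the 2 libraries richest in stromal transcripts (1.14e-09). B cell genes fell in 8 of 19 (0.000161, estimated 0.461) and germinal centre genes in 10 of 18 with 1 higher (0.000294, estimated 0.195). The stromal list fell in 5 of 26 (0.000294, estimated 0.803) and cholesterol genes in 3 of 17, 5 over the list alone (0.0336, estimated 0.803). Checkpoint molecules fell in 6 of 19 with 1 higher, 7 and 2 over the list alone (0.0336, estimated 0.461). MYC and ribosome genes rose in 13 of 20, 15 over the list alone (2.95e-06, estimated 0.195), and oxidative phosphorylation genes in 10 of 22, 14 over the list alone (2.95e-06, estimated 0.461). Chaperones rose in 8 of 15 with 1 lower, 11 over the list alone (0.000187, estimated 0.461), and cell cycle genes in 5 of 25 with 1 lower, 7 over the list alone (0.0312, estimated 0.803). NF-kB targets were not called (0.184), with 4 higher, such as NFKB2 (1.00), and TNFAIP2 (-2.10) lower. Without the 2 libraries richest in stromal transcripts, NF-kB targets were called higher, with 8 higher and 1 lower of 17 (0.00510), and the stromal list fell in 13 of 25 (2.90e-05). The calls of cell cycle genes (1 higher and 3 lower of 25, 0.931), checkpoint molecules (0.279) and cholesterol genes (0.0934) ended. Log2 fold changes were -0.91 for EBF1, -1.72 for FCRL1, -1.03 for BACH2, 0.64 for RRP9, 0.53 for CYC1, 1.22 for SDF2L1, -4.24 for LUM, 0.62 for E2F1, -0.63 for MSMO1, -1.42 for CD86 and 1.01 for ITGAL. Without 2D with TSC replicate 2, LUM was at -3.05, and without replicate 3, FCRL1 was at -0.93.

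DOHH2 in 3D with TSC held more NF-kB and immediate early RNA than in 2D alone and lost several transcripts almost wholly. Neither list call held with an estimated correlation (0.285 for both). NFKB2 (ENSG00000077150, chromosome 10, 102394110 to 102402529) rose from 29.2 ± 4.25 (mean ± SD, n = 4) to 162 ± 42.4 CPM (n = 5; log2 fold change 2.48, SE 0.21, edgeR adjusted p = 9.10e-06), and CBFA2T3 fell from 93.5 ± 6.09 to 1.84 ± 0.419 CPM (log2 fold change -5.68, SE 0.44, edgeR adjusted p = 8.41e-06). Of 16901 genes, 7891 changed, 4048 higher and 3843 lower, and 2691 by at least 2-fold. Among genes of at least 5 CPM in 2D alone, 5251 changed and 34.8% of them were higher, against 51.3%. Log2 fold changes were 1.75 for RELB, 1.49 for ITGAL, 2.26 for ITGB2, -6.46 for ZNF777, -5.34 for TCL1A, -5.22 for MLYCD, -5.12 for SARDH and -4.77 for NKX6-3. Without 3D with TSC replicates 1, 2 and 4 in turn they became -6.25 for MLYCD, -5.90 for SARDH and -6.93 for TCL1A. Genes at 0 in all monocultures were higher by at least 835-fold for IGFBP5, 368-fold for IGFBP4, 321-fold for IGFBP3, 285-fold for GREM1, 263-fold for BGN and 202-fold for S100A6. With 1 to 3 monoculture counts, the ratio was 873 (counting interval 299 to 4237) for TGFBI and 374 (103 to 3096) for MRC2. Without 3D with TSC replicate 2 these ratios were 457 and 164, and the bounds were 457, 228, 210, 155, 153 and 140-fold for IGFBP5, IGFBP4, IGFBP3, GREM1, BGN and S100A6. Leaving out a monoculture moved values the other way. The log2 fold change of TGFBI went from 9.56 to 12.36 without 2D alone replicate 1, and that of MRC2 from 8.27 to 10.55 without replicate 4. By a rule chosen after the data were seen, 16 genes of at least 5 CPM in 2D alone stood in 3D with TSC under 10% of that mean and past the threshold, and 13 genes of at least 5 CPM in 3D, with no 3D library under 30% of their mean, stood under 10% of the 3D mean in 2D alone.

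By list, in DOHH2 3D with TSC against 2D alone, NF-kB targets rose in 11 of 17 and 1 fell, 12 higher over the list alone (camera adjusted p = 9.60e-08, estimated 0.285), and immediate early genes rose in 14 of 17 (5.56e-07, estimated 0.285). Mitochondrially encoded genes rose in 12 of 13, 13 over the list alone (9.60e-08, estimated 0.443), and MHC class I genes in 9 of 14 (0.000313, estimated 0.443). The stromal list rose in 25 of 26 at a median log2 fold change of 6.22, or 5.71 with the genes at the floor set to their bound (3.25e-09, estimated 0.623). Germinal centre genes fell in 9 of 18 and 3 rose (0.00836, estimated 0.356), cell cycle genes fell in 12 of 25 and 1 rose (0.000395, estimated 0.750), and oxidative phosphorylation genes fell in 14 of 22, with 1 higher over the list alone (0.00383, estimated 0.750). MHC class II genes, 6 of 12 higher, were just short of the threshold (0.0528, and 0.0494 with DESeq2 size factors), and interferon genes, 5 higher and 4 lower of 21, were not called (0.676). Log2 fold changes were 5.82 for FOS, 0.89 for JUNB, 1.61 for MT-ND1, 0.73 for NLRC5, -1.11 for BACH2, -0.82 for BUB1, 0.85 for E2F1, -0.76 for SDHD and 0.63 for CIITA. Without the 2 libraries richest in stromal transcripts, 7972 genes changed, 7336 of them shared, and MHC class II genes were called higher in 6 of 12 (0.0114).

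**Figure D5:**
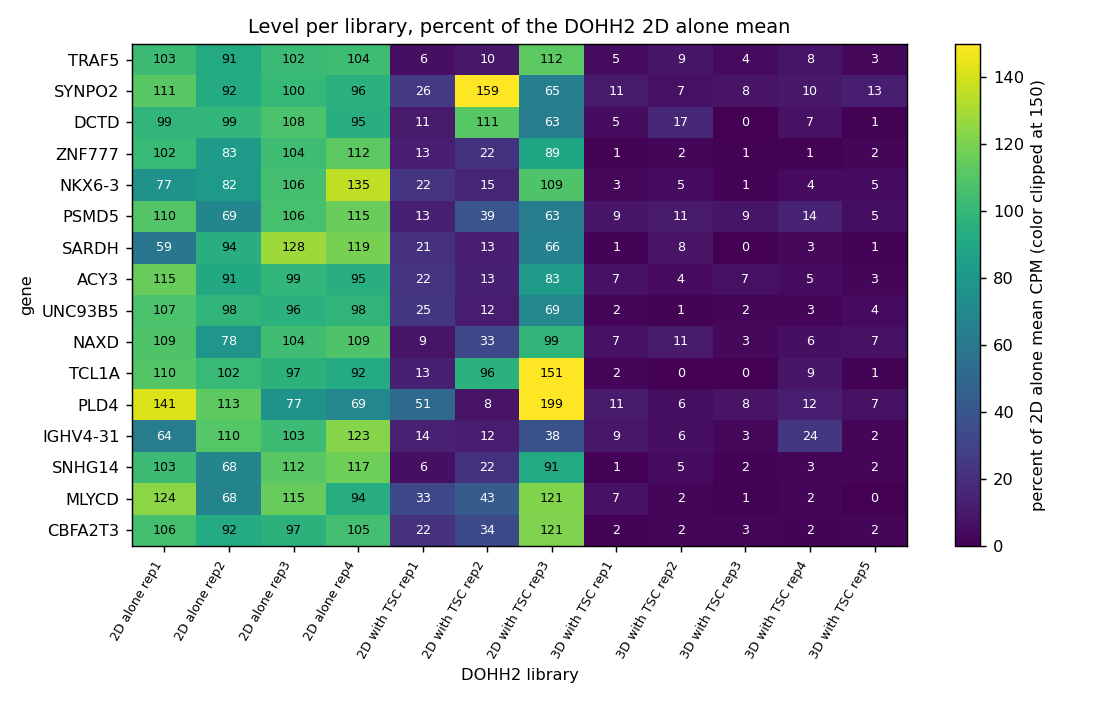
Level of 16 genes in each DOHH2 library as percent of their mean in DOHH2 2D alone, on a capped colour scale. Medians over the genes were 17.5%, 22.1% and 90.1% in 2D with TSC replicates 1, 2 and 3 and 2.36% to 5.58% in 3D.

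The effect of TSC in 2D differed between the lines, as DOHH2 minus HLY1, for 6831 of 21010 genes, 3611 higher and 3220 lower. Among genes of at least 5 CPM in DOHH2 2D alone the balance turned, with 1288 higher and 3086 lower of 4374 (29.4% higher). The RNA extraction kit is stated for DOHH2 only, so a difference in extraction between the lines was not ruled out, here or for 3D. Differences of log2 fold change were 3.07 for ASNS (SE 0.18, edgeR adjusted p = 2.76e-10), 3.12 for SLC7A11, -1.83 for PDIA4, -2.55 for JCHAIN, 1.76 for CIITA, 1.33 for MT-ND1, 3.00 for ITGB2 and -2.53 for PECAM1. Higher in DOHH2 were ATF4 targets in 17 of 20 (camera adjusted p = 4.64e-19, estimated 0.0219), mitochondrially encoded genes in 11 of 13, 12 over the list alone (3.34e-05, estimated 0.433), and MHC class II genes in 8 of 12, 9 over the list alone (0.000920, estimated 0.433). Interferon genes were higher in 7 of 22 (0.0174, estimated 0.635), but not called without the 2 libraries richest in stromal transcripts (5 of 22, 0.0577). The stromal list was higher in 12 of 26, 14 over the list alone (7.04e-07, estimated 0.433). Lower were cholesterol genes in 15 of 17, 16 over the list alone (1.04e-13, estimated 0.154), and chaperones in 12 of 15 with 1 higher (5.54e-12, estimated 0.0962). Lower too were oxidative phosphorylation genes in 19 of 22 with 1 higher, 20 over the list alone (4.85e-11, estimated 0.185), and MYC and ribosome genes in 16 of 20, 19 over the list alone (2.23e-09, estimated 0.0627). Cell cycle genes were lower in 16 of 25, 19 over the list alone (7.46e-07, estimated 0.433), and plasma cell genes in 6 of 16 with 3 higher (0.0174, estimated 0.261). Of genes called in both lines, 1396 had the same direction (1272.3 for independent lists) and 1352 the opposite (1272.6), with Pearson r 0.21 and Spearman rho 0.02 over 14977 genes. Among genes with a mean of at least 5 CPM these were 979 against 957.3 and 1016 against 1032.7, with r 0.0908. With library size as the only scaling, the median moved by 0.17 and 68.8% of these genes were higher, against 52.9%.

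The effect of 3D against 2D with TSC differed between the lines, as DOHH2 minus HLY1, for 4721 genes, 1617 higher and 3104 lower. Of 40 splits of the libraries, 2 gave as many, the real one included, but such splits can also remove the separate effects and cannot decide on an interaction. Differences of log2 fold change were -1.43 for MCM5 (SE 0.15, edgeR adjusted p = 1.02e-06), -4.98 for EGR1, -1.71 for BACH2, 1.63 for ITGAL, 1.64 for MANF, 1.84 for MZB1 and 2.08 for CDKN1A (2.67 without DOHH2 2D with TSC replicate 2). Lower were cell cycle genes in 24 of 25 (camera adjusted p = 2.49e-15, estimated 0.252) and MYC and ribosome genes in 10 of 20, 12 over the list alone (2.88e-05, estimated 0.247). Higher were chaperones in 9 of 15, 13 with 1 lower over the list alone (2.56e-12, estimated 0.177), and plasma cell genes in 7 of 16 with 2 lower (0.00109, estimated 0.177). MHC class I genes were higher in 6 of 14 with 2 lower (0.00459, estimated 0.456), p53 targets in 6 of 18 (0.00459, estimated 0.333) and MHC class II genes in 5 of 12 with 2 lower, 6 over the list alone (0.0176, estimated 0.689). Without the 2 libraries richest in stromal transcripts NF-kB targets were called higher too, 6 higher and 1 lower of 18 (0.0372). The balance of directions depended on the settings: 34.3% of these genes were higher, against 46.8% with DESeq2 size factors, 51.7% with library size only (median shift 0.14), 53.5% with no filter (prior degrees of freedom 32.0, against 5.18), 52.7% with the 5 CPM filter, 30.6% among genes of at least 5 CPM in DOHH2 2D alone, and 56.4% and 58.1% without HLY1 2D with TSC replicates 2 and 3. Of genes called in both lines, 1689 had the same direction (916.02 for independent lists) and 506 the opposite (920.31), with Pearson r and Spearman rho both 0.27.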

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

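All tests of stromal transcripts and of immediate early genes below, and those of a mislabelled library and of dilution, were chosen only after the results were seen, including the condition on genes that HLY1 makes alone, while the test of a different stock and the splits of the libraries were written before.

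A library that stood apart, by its gap to the next library relative to the range of its group, was found in 18 of 140 tests. Chance gives about 5% only for independent, normally spread values, and CPM of genes that vary together or lie near 0 are not such values. Only DOHH2 2D alone (4 libraries) and DOHH2 3D with TSC (5 libraries) were tested, and the groups of 3 libraries were not. In DOHH2 2D alone these were the total counts of replicate 1 (25833406), the mean log2 CPM of endoplasmic reticulum chaperones in replicate 2 (6.96, next library 6.85), of immediate early genes in replicate 1 (1.71, next 1.62) and of oxidative phosphorylation in replicate 2 (7.01, next 6.77), and the CPM of IL7R in replicate 2 (59.7), TGFBI in replicate 1 (0.1197) and MRC2 in replicate 4 (0.0626). The gaps of these list means were small. For TGFBI and MRC2 the other monocultures were at 0, so any count in 1 library would stand apart. In DOHH2 3D with TSC, replicate 2 stood apart with 1495 CPM of the stromal list, and with the CPM of IGFBP4 (24.4), GREM1 (21.3), FBN2 (14.7), COL12A1 (10.4), NT5E (3.75), SVEP1 (1.12), BGN (18.6), TGFBI (67.3) and MRC2 (21.6), while TCL1A stood apart in replicate 4 (1.05). Most of these genes are stromal transcripts of 1 library and so are not separate findings.

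Effects that differed between groups by a tested interaction were those of TSC in HLY1 between 3D and 2D (6558 genes), of TSC in 2D between the lines (6831 genes) and of 3D against 2D with TSC between the lines (4721 genes). The largest differences of log2 fold change of TSC in HLY1, 3D minus 2D, were 5.20 for BEST1, 4.65 for ESRP1, 4.37 for ASNSP1, 4.22 for PLOD2, 3.64 for LINC02475, -5.19 for CCL3, -5.11 for DUSP5, -4.23 for LINC00324, -4.19 for FUT7 and -4.03 for ST3GAL6. Without single libraries they became 3.95 for ESRP1 (2D alone replicate 3), -4.23 for CCL3 (3D alone replicate 2) and 3.01 for LINC02475 (3D with TSC replicate 1). The 20 genes with the largest differences between the lines were left out because a group held 3 or fewer counts of them.

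Splitting the same libraries in other ways tested whether chance alone gives as many changed genes. For each of the HLY1 comparisons of 2 groups, 1 of 10 splits, the real one, gave as many, and with 10 splits chance cannot be told apart from an effect. The highest other split gave 0 genes, except 166 for TSC in 3D against the real 306. Only the real split gave as many for TSC in DOHH2 2D (1 of 35 splits, highest other 0), DOHH2 3D against 2D with TSC (1 of 56, highest other 507) and DOHH2 3D with TSC against 2D alone (1 of 100 drawn, highest other 5677). The split with 5677 genes was close to the real one: it kept the 4 monocultures together and moved only 3D with TSC replicate 5 to their side. These counts argue against a chance arrangement of these libraries only. The labels do not say that replicates were separate cultures, so chance between cultures or stocks was not tested. For the interactions the splits cannot decide. Libraries were shuffled at random within each pair of groups, which could remove the separate effects as well as their difference, or leave the groups of 1 pair as they were. The split with 3066 genes below kept the real DOHH2 groups. As many genes came in 1 of 80 splits for the interaction in HLY1 (highest other 5776) and in 1 of 40 for the line difference of TSC in 2D (highest other 3066). For the line difference of 3D against 2D with TSC, 2 of 40 splits gave as many, and another split gave 5046 genes against 4721.

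Stromal transcripts in DOHH2 libraries from co-culture spread widely, 12.1 times between the libraries of 2D with TSC and 19.1 times in 3D with TSC. Sums here are TMM-scaled CPM of the list genes tested, unlike the unscaled sums given above. No relation with library size was found: the stromal sum did not follow total counts over the 8 libraries (Spearman rho -0.0714, exact permutation p = 0.882, and Pearson r -0.0985, p = 0.756, with r 0.0326 without the 2 farthest libraries). With 8 libraries a moderate relation is not excluded. The stromal genes rose and fell together, with a median r of 0.964 of each of 26 genes with the mean of the others (p = 0.000694, adjusted over 2 relations 0.00139, rho 0.893, p = 0.000273, adjusted 0.000546, and r 0.956 without the 2 farthest), consistent with RNA from stromal cells despite the sort. Transcription of these genes by DOHH2 cells met only part of its prediction. Every co-cultured library lay above the highest monoculture library, by a ratio of at least 7.82, but RNA from stromal cells would give this too. Libraries of a group were to lie within 2 times of each other, and this failed at 12.1 and 19.1 times. The test does not tell the sources apart for certain. The presence of TSC is the biological difference the design gives, and it remains untested as a cause inside the lymphoma cells.

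In DOHH2 3D with TSC, 16 genes fell under 10% of their monoculture level, and in 2D with TSC replicates 1 and 2, but not 3, most of them were low as well. A mislabelled monoculture library was excluded as replicate 3, since COL1A1 there was 487 times the highest monoculture library. Dilution of lymphoma RNA by stromal RNA was excluded, since B cell identity genes kept 91.7% of their monoculture level at the median. A different stock or subclone of the line cannot be told apart from an effect of culture: the 13 genes gained in 3D stood at 3.84% of the 3D mean in 2D with TSC replicate 3, but at 25.6% and 31.3% in replicates 1 and 2, where over 40% had been set. IGHG4 ran from 1892.4 to 3156.5 CPM and IGLV2-11 from 328 to 672 CPM over all DOHH2 libraries, while IGHV4-31 was among the 16 genes. TSC and 3D culture, which the design gives, remain open and untested.

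Immediate early genes were higher with TSC in both lines, by 12 of 14 members in HLY1 2D, 5 of 14 in HLY1 3D and 11 of 17 in DOHH2 2D. With an estimated correlation the list was called in none of them (camera adjusted p = 0.191, 0.165 and 0.152). RNA from stromal cells cannot be told apart from an effect of TSC by the summed rise of EGR1, FOS and FOSB over that of the stromal list. The ratio was 2.68 for HLY1 in 3D, and in 2D it was 0.0915 in HLY1 and 0.0318 in DOHH2. In HLY1, genes of at least 10 CPM in monoculture, FBN1 above all, gave 83.7% of the rise of the list in 3D and 80.3% in 2D, so the list does not measure stromal RNA alone there. In 3D the list rose by 97.9 CPM, 81.9 CPM of it from those genes, while EGR1, FOS and FOSB rose by 262 CPM. Without those genes the ratio would be larger, not smaller. The ratio rests on 3 genes, and their level in stromal cells in 3D was not measured, so it does not settle the source. In HLY1 3D, FOS also lost its call without each of 5 single libraries. A test of spheroid handling was dropped because both groups were spheroids, so handling that differed along with TSC was not tested. An earlier test with 1 fixed stromal profile was replaced after its result was seen, because the stromal profile was assumed to be the same in 2D and 3D. Time or stress between harvest and lysis was tested by HSPA1A and HSPA1B. In HLY1 2D both rose, by a mean log2 difference of 1.46 (HSPA1A 1.78, adjusted p = 6.68e-05, and HSPA1B 1.13, adjusted p = 1.26e-08), consistent with such stress, though an effect of TSC on these genes was not separated from it. In HLY1 3D the predicted rise of both genes was not seen, with a mean of 0.206 (HSPA1A 0.42, adjusted p = 0.559, and HSPA1B -0.01, adjusted p = 0.988). These markers thus gave no sign of such stress there. Only a fall of both genes had been set to count against it, so the test could not exclude stress where they did not change. In DOHH2 2D such stress cannot be told apart from an effect of TSC: the mean was 1.71, but HSPA1A rose by 4.24 (adjusted p = 0.0289) while HSPA1B stood at -0.82 (adjusted p = 0.0660). Both 2D tests, and the condition that both genes move the same way, were added with these values seen. On the mean alone, DOHH2 2D would have passed. The presence of TSC, which the design gives, remains open and untested.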

How the results depend on the processing

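Chosen only after the data were seen were library size as the only scaling, leaving out the 2 libraries richest in stromal transcripts, the stromal score as a covariate and the restriction to genes of at least 5 CPM in DOHH2 2D alone. Of 226 counts under an alternative, 198 stayed within 1.5 times of their reported value, 26 were lower and 2 higher. TSC in HLY1 3D gave 562 genes with DESeq2, and the cause was not tested. With no filter on low counts it gave 662, but that fit is no check in HLY1: its prior degrees of freedom were infinite, against 7.84, so each gene's own spread was ignored. Without the filter these degrees of freedom were 14.8, against 4.40, in DOHH2 and 32.0, against 5.18, over both lines. With a mean of at least 5 CPM, which tests fewer genes, the count was 8053 for HLY1 3D against 2D alone, 7901 for HLY1 3D with TSC against 2D alone, 3456 for TSC in DOHH2 2D and 5142 for DOHH2 3D with TSC against 2D alone. Among genes of at least 5 CPM in DOHH2 2D alone, again fewer, it was 3603 for TSC in DOHH2 2D, 5251 for DOHH2 3D with TSC against 2D alone and 4374 for the line difference of TSC in 2D, with 29.4% higher, against 52.9%. DOHH2 3D against 2D with TSC gave 2340 with only the 2 groups fitted (fewer samples) and 2404 with the stromal score, and the cause of the latter was not tested.

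Leaving out each library in turn gave 8151 to 9697 genes for TSC in HLY1 2D, 109 to 226 for TSC in HLY1 3D, 11987 to 12948 for HLY1 3D against 2D alone, 8829 to 9362 with TSC and 11824 to 12862 for 3D with TSC against 2D alone. In DOHH2 it gave 3500 to 5554 for TSC in 2D, 2849 to 3628 for 3D against 2D with TSC and 6330 to 7909 for 3D with TSC against 2D alone. The interaction in HLY1 gave 5654 to 7391 and the line differences 5732 to 7219 and 3471 to 5316. With fewer libraries fewer genes mostly pass, and in HLY1 3D with TSC the count depends on single libraries.

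With an estimated correlation, which allows for the correlation between genes of a list, 4 of 13 lists stayed called for TSC in HLY1 2D, 4 of 10 for TSC in HLY1 3D, 0 of 11, 0 of 14 and 0 of 12 for HLY1 3D against 2D alone, with TSC and 3D with TSC against 2D alone, 5 of 12 for the interaction, 0 of 12, 0 of 10 and 0 of 8 for DOHH2 TSC in 2D, 3D against 2D with TSC and 3D with TSC against 2D alone, and 1 of 11 and 0 of 7 for the line differences of TSC and of 3D. The overlaps of effects counted with a mean of at least 5 CPM were 85, 5018, 979 and 1330 genes, within 1.5 times of those reported. For TSC in 2D between the lines, 979 stood against 957.3 for independent lists, with 1016 in opposite directions against 1032.7, and Pearson r was 0.0908, not 0.21. For TSC in HLY1 2D and 3D, r was 0.00338, not 0.09. Fewer genes were tested, and the cause was not tested further.

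The replicate number as a block changed no count by over 1.5 times (9453 for TSC in HLY1 2D, 332 in HLY1 3D, 4568 in DOHH2 2D). It ended the call of the MHC class II list for TSC in DOHH2 2D (camera adjusted p = 0.0609), while another list was called in its place: 12 were called, 11 of them as before. Residual correlations of libraries sharing a number ran from -0.09 to 0.17 in HLY1 and from -0.17 to 0.51 in DOHH2. The library with the same number was the closest in 23 of 36 cases in HLY1, where chance gives 12, and in 5 of 18 in DOHH2, where chance gives 6. The labels give no pairing, and a shared number may still mark shared conditions in HLY1, which the block allows for. Among genes named, leaving out 1 library ended the call in 343 of 6959 checks and reversed 1: the log2 value of SDC1, line difference of 3D against 2D with stroma, ran from -4.09 without DOHH2 3D with TSC replicate 2 to 0.33 without DOHH2 2D with TSC replicate 2. Leaving out 1 library moved the fold change by over 1.5 times in 144 of 6959 checks, for 117 of 823 values. Calls ended in 7 of 811 checks with DESeq2, 8 of 823 with DESeq2 size factors, 21 of 673 with the 5 CPM filter, 27 of 823 with library size only, 18 of 823 with no filter (no check in HLY1), 19 of 593 with only 2 groups, 17 of 823 with the block, 15 of 70 with the stromal score, 23 of 371 without the 2 stromal-rich libraries and 1 of 780 without genes that stromal RNA could raise. Leaving out genes that stromal RNA could raise only adjusted the same p-values again, so calls could hardly end, and it is no test of stromal RNA. Depth limits genes of low counts: a gene at 0 in a group of 3 or 4 libraries gives only a lower bound.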

Other observations

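Lists that the comparisons left without a call still held changed genes, given here with log2 fold changes and camera adjusted p. Of all genes tested, 49.3% changed for TSC in HLY1 2D, 67.2% for HLY1 3D against 2D alone and 46.7% for DOHH2 3D with TSC against 2D alone. Changed members alone therefore do not set a list apart. With TSC in HLY1 2D, germinal centre genes rose in 5 and fell in 1 of 13 (0.118), hypoxia and glycolysis genes rose in 10 and fell in 4 of 25 (0.0901), among them PFKFB3 (1.55) and NDRG1 (0.70), and B cell identity genes rose in 3 and fell in 2 of 14 (0.467). Apoptosis regulators rose in 6 and fell in 5 of 14, with the median and the test differing in sign (0.904), among them BCL2L11 (1.02), PMAIP1 (-1.35) and BBC3 (-1.36). In HLY1 3D against 2D alone, hypoxia and glycolysis genes rose in 9 and fell in 6 of 25 (0.305, with the sign differing between median, mean and test), among them TPI1 (1.11) and NDRG1 (1.29). In DOHH2 3D with TSC against 2D alone, apoptosis regulators rose in 3 and fell in 4 of 14 (0.861), among them BAX (0.65) and BBC3 (0.92), and p53 targets rose in 5 and fell in 5 of 18 (0.798), among them TNFRSF10B (0.72) and FAS (2.14).

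A hypothesis chosen after the result was seen is that TSC in 2D and 3D culture alone may move the same genes in HLY1. Of 18843 genes, 3109 were higher in both (1393 for independent lists) and 3641 lower in both (1736.3), and Pearson r of the fold changes across genes was 0.636. Both comparisons share the 3 monoculture libraries in 2D, which alone gave r 0.475 in 10 simulations of unchanged groups. The covariance of the fold changes was 0.586, against 0.0367 in the simulations, a difference of 0.550, so the shared controls do not account for it in simulated groups. With 3 controls, no split could give each comparison 2 of its own, so part of the excess may still come from them.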
